A study of Mus musculus with 36 samples.

How the data were processed

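Polyadenylated RNA was sequenced from 18 libraries of sorted mouse myeloid progenitors, 6 of embryonic fibroblasts and 12 of cultured Lin-Kit+ bone marrow cells, per the labels' protocols with a TruSeq kit for the progenitors and fibroblasts and a NEBNext Ultra kit for the Lin-Kit+ cells. Each library came as a list of the same 219945 introns. The deposited tables hold, per the file headers, whole-number counts of reads at the lower-coordinate and higher-coordinate exon-intron boundary and of reads spliced across the intron. The authors' tables also give, per the file headers, the fraction of each intron that is covered and a percent value. Computed from the counts, that percent equals 100 times the exon-intron reads divided by exon-intron reads plus 2 times the spliced reads in every intron of every library. The genome build was mm10 per the submitters' processing notes, and the aligner and counter are not given in the sources used here. No strand was recorded for the counting, so reads of overlapping and antisense genes cannot be told apart, and reads shared with near-identical copies of a gene are uncertain.

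All 219945 introns matched annotated introns of GENCODE M21, in 31747 genes, with 1887 introns assigned to more than 1 gene. A read that spans several introns is counted at each, so spliced counts summed over a gene exceed its number of reads, and a gene with many introns gives counts that are not independent. Sums over introns are therefore precise only as far as the spread between libraries shows, and counting intervals were not used for them. Genes without a listed intron, Zrsr1 among them, have no value. Spliced counts were 44083233 to 84832431 per progenitor library, 43514139 to 61124920 per fibroblast library and 30481450 to 43345548 per Lin-Kit+ library. No pair of libraries within a group held identical counts.

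Groups followed the labels. For genes, spliced counts were summed over introns and tested with edgeR 4.0.16 (quasi-likelihood test, TMM, filterByExpr, Benjamini-Hochberg adjustment, threshold 0.05) in R 4.3.3, with 1 coefficient per group in 1 fit for the progenitors, 1 for fibroblasts and 1 for Lin-Kit+ cells. Hairpin comparisons used the mean of sh1 and sh10. CPM values are spliced counts scaled to the total of spliced counts of the library, without TMM factors. Gene lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01, and again with an estimated correlation. Of 32 lists fixed for cell types, pathways and complexes, no call by camera without a block held with the estimated correlation in any comparison of genotypes or hairpins, and no called list had a median, mean and test that differed in sign.

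For introns, exon-intron and spliced counts were the 2 features of an intron in edgeR's diffSpliceDGE, over introns that passed filterByExpr on both. This is the test fixed before the data were examined for transcripts that retain an intron, applied here to introns because the tables are not per transcript. The size of an effect is the difference between group means of log2((exon-intron + 0.5) / (spliced + 0.5)), with its standard error from limma. No genome sequence was used. Transcript sequences gave both ends of 10301 introns, those overlapped by an exon of another transcript, and only these were classed. An intron was U12-type when its first 8 bases matched the U12 5′ site with at most 1 mismatch, it ended in AG or AC and its last 40 bases held a branch point motif of 8 bases with at most 2 mismatches. This gave 67 introns in 64 genes, of which 60, 52 and 58 were tested in progenitors, fibroblasts and Lin-Kit+ cells. The class was compared with all other classed introns by camera on the log2 ratios, as 1 set per comparison over 12 comparisons, without adjustment across comparisons.

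In Lin-Kit+ cells the labels name a shared experiment, and libraries of the same experiment deviated together (correlations of 0.371 to 0.466 over 30 pairs). Each group was centred on its 2 libraries, so every correlation occurs once in each experiment and the 30 pairs are not separate values. Fits with the experiment as a block are given beside the unblocked ones where they change a call. Libraries of 1 genotype and number in CMP, GMP and MEP come from the same mouse. Numbers were not treated as pairs of KO and WT mice, though same-numbered libraries correlated best in CMP and MEP.

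Named genes were fixed by a rule. They are Zrsr2 and Zrsr1, up to 10 genes per direction with the largest change among those called, without overlap between the libraries of the groups and with at least 5 CPM in 1 group, leaving out predicted and unnamed genes, and up to 4 members of each described list with the smallest p. They also include up to 10 genes called in all 3 progenitor types in 1 direction and up to 10 introns with the smallest p. Examples in the text are taken from these, apart from called genes of which the text says that they were named after their values were seen. Some genes that the rule names are not reported here.

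Scripts were tested on simulated counts with 200 genes or introns changed, 100 at a log2 change of 1 and 100 at 2. For KO against WT in CMP, 60 and 86 of the 100 genes were recovered among 16755 and 5 and 50 of the 100 introns among 62278. In MEF, 33 and 79 genes were recovered among 16119 and 8 and 74 introns among 32573. In the measured MEF libraries edgeR did not call Zrsr2 at a log2 change of -6.54, so the shares for MEF may be too high. In Lin-Kit+ cells with the control hairpin, without a block, 0 and 13 genes were recovered among 16661 and 0 and 0 introns among 46630. A simulated shift of 0.5 in 60 introns gave a camera p of 1.07e-08, and no shift gave 0.872. Introns were drawn independently and once per setting, so this does not test the preset correlation. The estimated correlation of the U12-type class was 0.080 in progenitors and 0.170 in Lin-Kit+ cells without a block.

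Alternatives were another normalization and other filters, DESeq2 1.42.0, limma-voom, the mouse as a random effect, the replicate block, fits on the groups compared only, each hairpin alone, other rules for U12-type introns, limma on the log2 ratio and leaving out each library. Chosen after the data were seen were the comparison of KO with WT under Zrsr1 hairpins, the test of the U12-type class by camera and its estimated correlation, the log2 ratio as effect size, the rule with the exact 5′ site only, the paired quasi-likelihood model of retention, sums over introns that overlap no other listed intron, the median intron count per gene, the alternatives for differences between WT cell types, single hairpins in the intron tests, blocked fits with DESeq2, limma-voom, the median intron count or without 1 library, and lists of kidney and other organ genes. Tables were read in R with version 1.17.8 of data.table and with numpy 2.4.6 and pandas 2.3.3 in Python 3.11.15, and plots were drawn with matplotlib 3.10.9.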

Results

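Polyadenylated RNA of 36 mouse libraries was measured as reads over introns. Sorted common myeloid progenitors (CMP), granulocyte-monocyte progenitors (GMP) and megakaryocyte-erythroid progenitors (MEP) came from 3 wild-type (WT) and 3 Zrsr2 knockout (KO) male littermates, and embryonic fibroblasts (MEF) from 3 WT and 3 KO male embryos. Bone marrow cells negative for lineage markers and positive for Kit (Lin-Kit+), a fraction rich in stem and progenitor cells, were taken from WT or KO mice and cultured ex vivo. They carried a control hairpin RNA or 1 of 2 hairpins against Zrsr1, sh1 or sh10. Experiments 1 and 2 gave 2 libraries per group and 12 in all. The libraries held 44083233 to 84832431 spliced counts in progenitors, 43514139 to 61124920 in MEF and 30481450 to 43345548 in Lin-Kit+ cells. Counts of exon-intron reads were far lower: 2465950 to 4620784 in progenitors, 1508406 to 1983413 in MEF, 1336774 to 1923401 in experiment 1 and 1150967 to 1438269 in experiment 2 of the Lin-Kit+ cells. Among introns with at least 20 exon-intron reads, 10.7 to 16.9% had none at 1 of the 2 ends in experiment 1 and 30.6 to 37.0% in experiment 2. Nothing in the labels says whether the Lin-Kit+ libraries of different experiments came from separate mice, so their p-values measure the spread between these libraries.

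Zrsr2, which encodes a protein that recognises the 3′ splice site of U12-type introns, was the gene targeted in the KO. Spliced counts summed over its introns (mm10, chromosome X, 163935443 to 163958661) numbered 0 to 2 per KO library in CMP, 0 to 4 in GMP and 1 to 5 in MEP. The WT libraries held 1970 to 2147, 1192 to 1477 and 1648 to 1857. Its level was 0.0151 ± 0.0262 CPM (SD, n = 3) in KO CMP against 31.6 ± 3.59 in WT CMP. It was 0.0203 ± 0.0351 against 25.8 ± 1.93 in GMP and 0.0539 ± 0.0344 against 26.7 ± 1.55 in MEP. In MEF it was 0.277 ± 0.244 against 25.8 ± 2.63, with summed counts of 0 to 20 per KO library. KO Lin-Kit+ cells held 0.809 ± 1.004 CPM with the control hairpin (n = 2, summed counts of 3 and 57), 0.740 ± 0.890 with sh10 and 0.112 ± 0.0327 with sh1. WT Lin-Kit+ cells held 24.98 ± 1.24, 24.5 ± 1.08 and 19.2 ± 0.0941. Zrsr2 fell in KO by 10.94 on the log2 scale in CMP (SE 0.54, edgeR adjusted p = 1.92e-08), by 10.25 in GMP (SE 0.50, adjusted p = 1.68e-08) and by 8.96 in MEP (SE 0.45, adjusted p = 2.79e-08). With KO counts this near 0 the size of the change is loosely fixed: leaving out 1 library gave -13.84 to -10.38 in CMP and -13.66 to -9.57 in GMP, the lowest without KO1, the only KO library with a count in either. The log2 change of Zrsr2 was -6.54 in MEF (SE 0.80) and -4.77 in Lin-Kit+ cells with the control hairpin (SE 1.17), where edgeR gave an adjusted p of 1 in both, at unadjusted p of 1.06e-04 and 2.88e-03. Zrsr1, the related gene targeted by the hairpins, has no listed intron, so its knockdown was not measurable here.

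The first question was whether U12-type introns, the minor class removed by a separate spliceosome, were retained more in KO progenitors. Retention was the deposited percent value, 100 times the exon-intron reads of both ends over those reads plus 2 times the spliced reads, and changes are log2 ratios of exon-intron to spliced reads. In CMP the 60 measured introns classed as U12-type had a mean retention of 14.5 ± 0.543% in KO and 11.2 ± 0.664% in WT (SD, n = 3 mice each). In GMP the values were 13.5 ± 2.21% and 10.01 ± 0.258%, and in MEP 11.5 ± 0.886% and 9.20 ± 0.828%. The 7132 other introns classed by sequence lay at 13.3 ± 0.504% in KO and 12.9 ± 0.830% in WT CMP. They lay at 11.2 ± 1.77% and 11.8 ± 0.382% in GMP and at 11.3 ± 0.368% and 11.2 ± 1.14% in MEP. The median log2 ratio change of U12-type introns was 0.43 in CMP, 0.38 in GMP and 0.30 in MEP, above that of other introns by 0.35, 0.50 and 0.29. Under a strict rule that allows no mismatch in the 5′ site (42 introns) the shifts were 0.40, 0.47 and 0.57, so the order of the cell types depends on the rule. Of the 60 introns, 45, 44 and 45 were higher in KO. The U12-type class rose relative to other introns in each cell type by limma's camera test (p = 7.55e-07, 5.98e-18 and 1.57e-08), and also with an estimated correlation (p = 0.0227, 6.46e-04 and 0.0113). The shift in GMP minus that in CMP was 0.26, that in MEP minus CMP 0.04 and that in MEP minus GMP -0.11, and none of these 3 differences passed the camera test with all libraries. With the exact 5′ site only, they were 0.04, -0.13 and -0.10. The difference between GMP and CMP passed without KO_CMP2, KO_GMP3, WT_GMP1 or WT_GMP2 (shifts of 0.25 to 0.28) and that between MEP and GMP without KO_GMP3, WT_GMP1 or WT_MEP1 (-0.28 to -0.17). Only introns overlapped by an exon of another transcript could be classed, which makes the class a selected part of all U12-type introns.

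**Figure D1:**
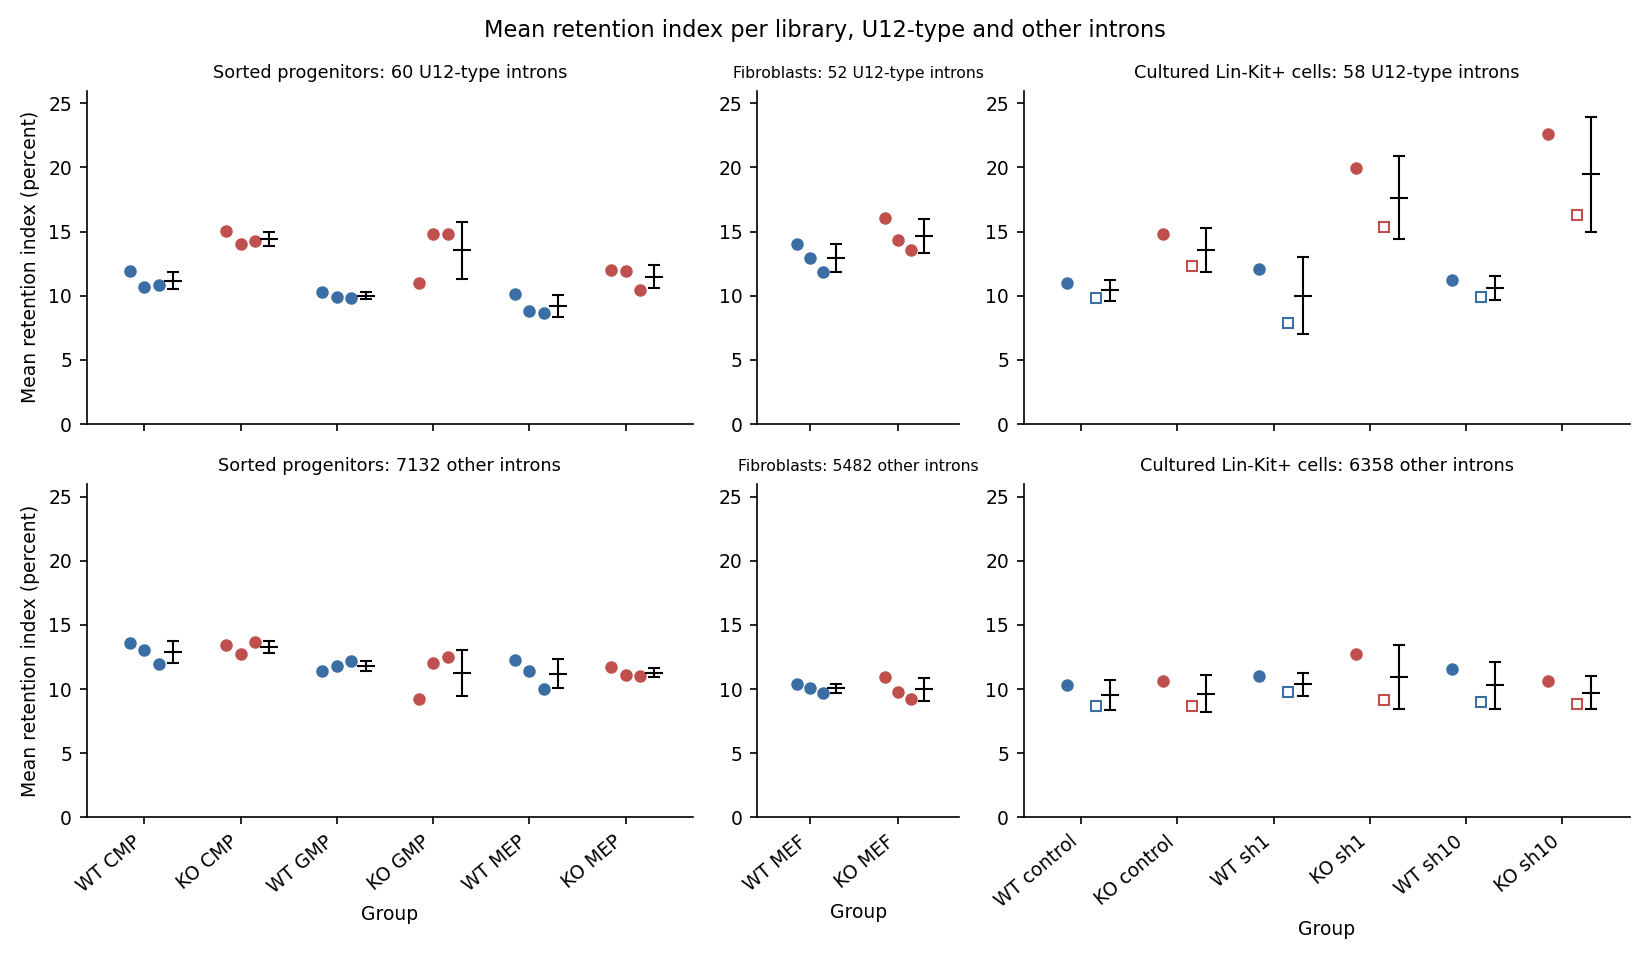
Mean retention (percent, with spliced reads counted 2 times in the denominator) of U12-type introns in each library, by group, with WT in blue and KO in red; open squares are experiment 2 of the Lin-Kit+ cells, filled circles all other libraries, and black marks with bars the mean ± SD. KO CMP libraries lie between 14.1 and 15.1%, above the WT CMP libraries at 10.7 to 11.9%.

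Pola2, the B subunit of the DNA polymerase alpha-primase complex, had the intron that passed the test over all introns in all 3 progenitor types. Intron 3 of Pola2 (17 introns, chromosome 19, 5958876 to 5959032, 157 bases, 5′ end GTATCCTT, U12-type) was retained at 13.5 ± 6.57% in KO against 3.04 ± 0.839% in WT CMP (SD, n = 3). The values were 18.8 ± 1.56% against 2.07 ± 0.631% in GMP and 9.46 ± 1.21% against 1.17 ± 0.919% in MEP. Its log2 ratio rose by 2.20 (SE 0.57, edgeR adjusted p = 0.0227), 3.46 (SE 0.57, adjusted p = 1.44e-05) and 3.44 (SE 0.57, adjusted p = 3.77e-05). Msh3, a mismatch repair gene, carried the other intron called in CMP. Intron 6 of its 23 (chromosome 13, 92345102 to 92346732, 5′ end ATATCCTT, U12-type) rose by 3.25 (SE 0.52, adjusted p = 0.0227), from 5.81 ± 1.23% in WT to 37.4 ± 5.01% in KO. In GMP, intron 2 of the nuclear import receptor gene Tnpo2 (chromosome 8, 85038490 to 85040461) rose from 1.63 ± 0.510% to 10.7 ± 2.78%. Intron 2 of the clathrin adaptor gene Ap1m1 (chromosome 8, 72246796 to 72249112) rose from 1.32 ± 0.543% to 5.82 ± 1.36%. Intron 2 of the endosomal sorting gene Vps25 (chromosome 11, 101254177 to 101254918) rose from 1.23 ± 0.530% to 4.55 ± 1.45%. Each of these 3 had an edgeR adjusted p of 0.0464. In MEP, intron 4 of the translation factor gene Mcts1 (chromosome X, 38606073 to 38611765, 5′ end GTATCCTT) rose from 11.7 ± 2.96% to 27.9 ± 3.98% (adjusted p = 0.0214). Intron 6 of the proteasome subunit gene Psma1 (chromosome 7, 114269851 to 114270332) rose from 0.399 ± 0.0238% to 1.41 ± 0.0780% (adjusted p = 0.0205). The introns called were thus 2 in CMP, 4 in GMP and 3 in MEP of 62278 tested, all higher in KO. Of these, 2, 1 and 1 were U12-type by the main rule, and 2, 1 and 2 by the exact 5′ site only. The rest were classed as other or could not be classed. No intron passed in CMP without KO1, KO2, WT1, WT2 or WT3, 2 passed in GMP without KO1 and 1 without any other library, and 1 passed in MEP without KO1, KO3, WT1 or WT3. With a paired quasi-likelihood model 0 passed in any of the 3.

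Adjusted over the list alone, 2 of the 60 U12-type introns passed in CMP (Msh3 and Pola2), 3 in GMP and 4 in MEP, all with higher retention in KO. In GMP, intron 3 of the RING finger gene Cgrrf1 (chromosome 14, 46846052 to 46846184) rose by 2.68 (SE 0.51, edgeR p adjusted over the list alone = 0.0116), from 2.51 ± 0.136% to 15.2 ± 2.55%. Intron 13 of Vps16, a gene of lysosomal fusion (chromosome 2, 130440580 to 130440706, 5′ end GTATCCCT), rose by 1.22 (SE 0.35, 0.0116 in the same test), from 15.4 ± 3.74% to 29.8 ± 6.78%. In MEP the Cgrrf1 intron rose from 0.993 ± 0.531% to 11.4 ± 4.63%. Intron 2 of the inositol phosphatase gene Inpp5b (chromosome 4, 124742591 to 124742935) rose from 0.275 ± 0.477% to 11.6 ± 6.90% and intron 1 of the small GTPase gene Arl16 (chromosome 11, 120467241 to 120467362) from 4.31 ± 1.14% to 19.998 ± 3.22%. Their list-adjusted edgeR p values were 8.53e-04, 6.51e-03 and 0.0348. The count in CMP was 4 without KO2 and 5 without WT1; in GMP it was 5 without KO1, 7 without WT1 and 1 without WT2 or WT3; in MEP it was 2 without WT1. Vps16 failed in GMP without KO2 (list-adjusted p = 0.142), Cgrrf1 without KO3 (0.0515) and both without WT2 or WT3 (0.0714 to 0.0873), and in MEP Inpp5b failed without WT1 (0.107) and Arl16 without any 1 of the 6 libraries (0.0619 to 0.165). Spliced counts of the 63 genes with a U12-type intron, that intron included, had a median log2 change of -0.0018 in CMP, -0.021 in GMP and 0.0097 in MEP. None of the 3 passed (camera adjusted p = 0.562, 0.884 and 0.742).

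**Figure D2:**
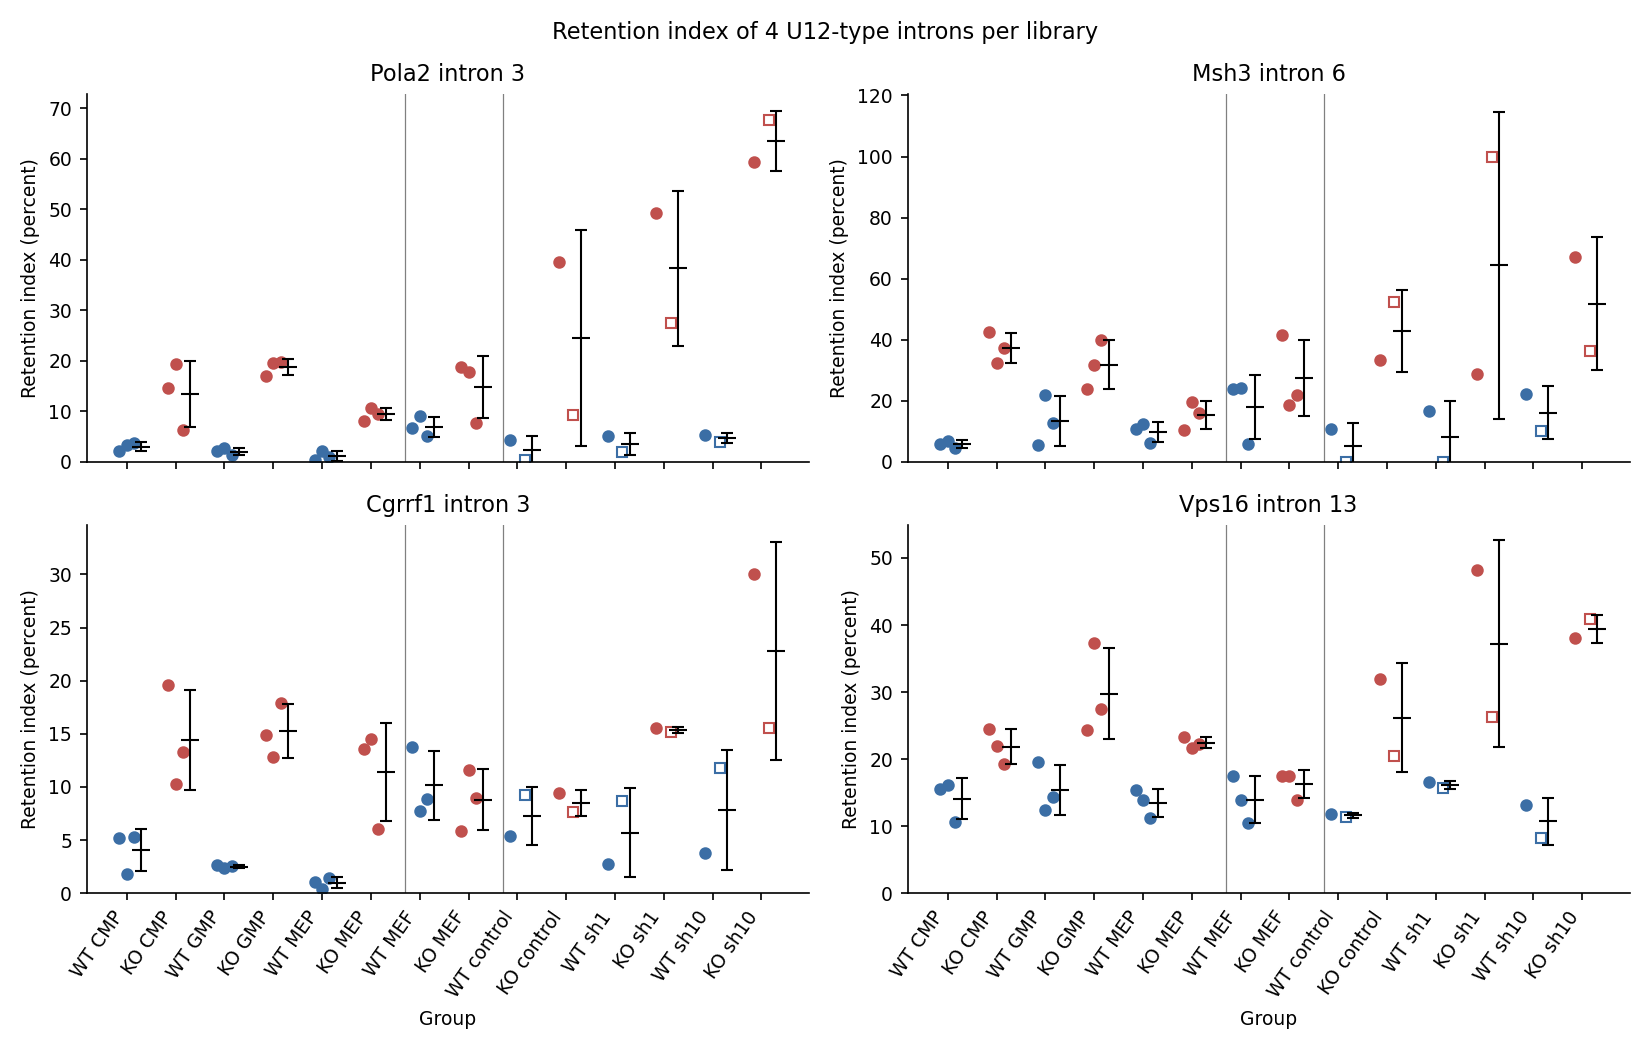
Retention (percent, with spliced reads counted 2 times in the denominator) per library of the named introns in each group, with WT in blue and KO in red; filled circles are experiment 1 or single-experiment libraries, open squares experiment 2, and black marks with bars the mean ± SD. Pola2 intron 3 is higher in KO than in WT in CMP, GMP and MEP, at means of 13.5, 18.8 and 9.46% against 3.04, 2.07 and 1.17%.

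KO and WT CMP were also compared at the level of spliced counts per gene. Sec14l1, which encodes a lipid-binding protein of the SEC14 family (chromosome 11, 117115168 to 117159268), fell by 0.80 on the log2 scale (SE 0.10, edgeR adjusted p = 9.17e-03), from 30.3 ± 2.91 to 17.5 ± 1.12 CPM (SD, n = 3). Pcyt2, an enzyme of phosphatidylethanolamine synthesis with a U12-type intron (chromosome 11, 120610087 to 120617936), rose by 0.44 (SE 0.06, adjusted p = 0.0213), from 95.8 ± 2.57 to 131 ± 0.774 CPM. With Zrsr2 these were the 3 genes called of 17361 tested, and 1032 had an unadjusted p under 0.05. DESeq2 called 48 genes, and edgeR 1 in a fit on these 2 groups alone or on the median intron count per gene, where Sec14l1 and Pcyt2 failed. Among gene lists fixed before the data were examined, markers of mature neutrophils rose (13 of 15 higher, median 0.84, camera adjusted p = 1.68e-04; adjusted p = 0.836 with an estimated correlation). Lactoferrin (Ltf), a granule protein, was at 32.5 ± 17.8 CPM in KO and 10.9 ± 3.21 in WT, and the gelatinase gene Mmp9 had a log2 change of 1.62. Markers of granulocyte-monocyte progenitors (17 of 19 higher, median 0.17, adjusted p = 9.67e-03) and of megakaryocytes (15 of 15 higher, median 0.21, adjusted p = 1.57e-03) rose as well. Both had an adjusted p of 0.836 with an estimated correlation. Elastase (Elane) was at 77.0 ± 32.5 against 44.8 ± 12.02 CPM. No member of these 3 lists passed over all genes. Without KO1, KO2 or WT3 the count of genes was 1. Pcyt2 failed without any 1 of the 6 libraries (adjusted p 0.0670 to 0.210), and Sec14l1 failed without KO1, KO2, KO3 or WT3 (0.0572 to 0.0887).

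In GMP, Sec14l1 fell by 0.79 (SE 0.10, edgeR adjusted p = 7.94e-03), from 27.3 ± 1.15 to 15.8 ± 1.91 CPM (SD, n = 3). Spag1, which encodes an assembly factor of ciliary dynein arms (chromosome 15, 36178099 to 36235621), rose by 1.62 (SE 0.20, adjusted p = 4.49e-03), from 2.41 ± 0.155 to 7.42 ± 1.88 CPM. These were, with Zrsr2, the 3 genes called, and 444 had an unadjusted p under 0.05. DESeq2 called 20, and edgeR 1 in a fit on these 2 groups alone or on the median intron count per gene, where Sec14l1 and Spag1 failed. Neutrophil markers fell (14 of 15 lower, median -0.54, camera adjusted p = 7.75e-03), with Cd177, a neutrophil surface protein, at -0.85 and Wfdc21 at -0.70. Genes of the unfolded protein and integrated stress responses fell (19 of 23 lower, median -0.13, adjusted p = 7.75e-03), with the stress factor Nupr1 at -1.56 and the chaperone Hspa5 at -0.20. Both had an adjusted p of 0.990 with an estimated correlation. The 4 measured genes of the male and female list were higher in KO (median 0.24, adjusted p = 8.03e-04, and 0.592 with an estimated correlation), among them the Y-linked translation factor Eif2s3y at 0.43. The gene count was 5 without KO1 or KO2 and 1 without WT1 or WT3. Spag1 and Sec14l1 failed without WT1 (adjusted p = 0.0504 for both) or WT3 (0.0632 for both). Sec14l1 also failed without KO3 (0.0773), and Spag1 with limma-voom (0.0890).

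MEP had 6 genes higher and 2 lower in KO, of which Zrsr2 and Sec14l1 were the lower ones. Sec14l1 fell by 0.82 (SE 0.10, edgeR adjusted p = 3.35e-03), from 31.4 ± 2.99 to 18.1 ± 1.02 CPM (SD, n = 3). Spag1 rose by 1.25 (SE 0.20, adjusted p = 0.0281), from 3.40 ± 0.105 to 8.24 ± 0.870. The other 5 genes, named after their values were seen because they lay under the expression limit for naming, were all near the floor of detection in WT MEP. Syne2, a spectrin-repeat protein of the nuclear envelope (chromosome 12, 75818134 to 76110926), rose by 3.95 (SE 0.30, adjusted p = 5.81e-06), from 0.167 ± 0.0152 to 2.67 ± 0.755 CPM. Rdh12, a retinol dehydrogenase (chromosome 12, 79208914 to 79222665), rose by 2.76 (SE 0.32, adjusted p = 1.49e-03), and F10, coagulation factor X (chromosome 8, 13037308 to 13056676), by 3.05 (SE 0.40, adjusted p = 4.32e-03). These sizes are loosely fixed: over the alternatives they were 2.485 to 5.318 for Rdh12 and 2.725 to 5.581 for F10. Irf5, a transcription factor of innate immunity (chromosome 6, 29526625 to 29541871), rose by 2.15 (SE 0.36, adjusted p = 0.0476), from 0.249 ± 0.127 to 1.13 ± 0.637 CPM. Tlr7, an endosomal receptor for single-stranded RNA (chromosome X, 167304929 to 167330558), had spliced counts, summed over its 5 introns, of 10 to 27 in the KO libraries and 0 in every WT library (edgeR adjusted p = 0.0281). No intron of these 5 genes held more than 17 spliced reads in a KO MEP library. In WT mice all 5 were lower in MEP than in CMP by edgeR, with log2 changes of -6.18 for Syne2, -5.34 for Rdh12, -5.53 for F10 and -5.92 for Irf5. Tlr7 had summed counts of 91 to 224 in WT CMP.

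Heme synthesis genes fell in KO MEP (14 of 16 lower, median -0.09, camera adjusted p = 0.0112), with erythroid aminolevulinate synthase (Alas2) at -0.48 and Uros at -0.21. Heat shock genes (8 of 8 lower, median -0.15, adjusted p = 0.0202, Hsph1 at -0.31) and E2F targets of DNA replication (16 of 20 lower, median -0.08, adjusted p = 0.0181, Uhrf1 at -0.15) fell too. The 4 genes of the male and female list were higher (median 0.17, adjusted p = 0.0112, Eif2s3y at 0.50). With an estimated correlation the adjusted p of E2F targets was 0.853 and that of the other 3 lists 0.636. At an unadjusted p under 0.05 there were 769 genes in MEP, and DESeq2 called 80. A fit on these 2 groups alone called 1, where Sec14l1 and Spag1 (adjusted p = 0.296 for both), Syne2 (0.0927), Rdh12, F10 and Irf5 failed, and the median intron count per gene gave 2. Limma-voom left 2 genes in MEP, Zrsr2 and Sec14l1, with Spag1 at an adjusted p of 0.148 and Syne2 at 0.912. The count was 15 without KO3 or WT1. Spag1 failed without KO1, KO2 or any WT library (adjusted p 0.0525 to 0.102), Tlr7 without KO1, KO2 or any WT library (0.0517 to 0.0877), and Irf5 without KO2, WT2 or WT3 (0.0656 to 0.121).

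Whether the KO effect differed between progenitor types was tested as an interaction; each mouse gave 1 library of each type. Syne2 differed between MEP and CMP by 3.89 (SE 0.38, edgeR adjusted p = 4.05e-04) and between MEP and GMP by 3.90 (SE 0.38, adjusted p = 4.04e-04). Rdh12 differed by 2.83 (SE 0.41, adjusted p = 0.0371) and 2.88 (SE 0.41, adjusted p = 0.0294). No gene differed between GMP and CMP by edgeR or limma-voom, with 849 at an unadjusted p under 0.05 and 10 called by DESeq2, which called 46 in MEP against CMP and 39 in MEP against GMP. Neutrophil markers differed between GMP and CMP by a median of -1.47 (14 of 15 lower, camera adjusted p = 1.37e-05) and markers of granulocyte-monocyte progenitors by -0.26 (15 of 19 lower, adjusted p = 0.0285). Both had an adjusted p of 0.991 with an estimated correlation. With the mouse number as a block the MEP and CMP comparison called 1 gene, with Rdh12 at an adjusted p of 0.0835, and 1 list. MEP against GMP called 3 lists where the fit without it called 0. With the mouse as a random effect or with limma-voom neither gene passed in either comparison. Intron 14 of the endosomal gene Washc5 (28 introns, chromosome 15, 59349404 to 59350131) was the only intron with a called difference, between MEP and CMP (adjusted p = 0.0333). Its retention was 0% in every KO MEP and WT CMP library, 0.495 to 3.58% in KO CMP and 0.386 to 2.53% in WT MEP. The call was lost with the mouse number as a block (adjusted p = 0.117) and without any 1 of 10 of the 12 libraries. Without KO_GMP1 the GMP and CMP comparison called 1 gene. Without KO_MEP1 or KO_MEP3 the count was 4 in MEP against CMP, and 5 and 6 in MEP against GMP. Rdh12 failed in the MEP and CMP comparison without KO_CMP1, KO_CMP2, KO_CMP3, KO_MEP2, KO_MEP3, WT_CMP1, WT_CMP2, WT_CMP3, WT_MEP1 or WT_MEP3 (adjusted p 0.0502 to 0.198). It failed in the MEP and GMP comparison without any library but KO_MEP1, WT_MEP2 or KO_MEP3 (0.0636 to 0.190).

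WT libraries also gave the differences between the progenitor types themselves, in a fit without a term for the mouse. GMP held more of the granulocyte genes Elane (3109 ± 586 against 44.8 ± 12.02 CPM, SD, n = 3) and Cebpe (9.72 ± 2.67 against 0.125 ± 0.0415) than CMP. Elane rose by 6.25 (SE 0.37, edgeR adjusted p = 6.06e-09) and Ms4a3, another granulocyte gene, by 5.52 (SE 0.28, 9.06e-10). The lymphoid polymerase gene Dntt fell by 8.10 (SE 0.94, 7.82e-06) and the carbonic anhydrase gene Car1 by 7.07 (SE 0.51, 4.64e-08). MEP held more of the erythropoietin receptor Epor (log2 2.78) and of Klf1, a transcription factor of red cells (2.84), than CMP. It held more of the copper transporter gene Atp7b (log2 4.29, SE 0.49, adjusted p = 1.89e-06) and less of Ly86 (log2 -7.93, SE 0.57, adjusted p = 1.11e-08). In all, 2158 genes were higher and 2132 lower in GMP, and 3652 higher and 4414 lower in MEP. Of the lists, markers of granulocyte-monocyte progenitors rose in GMP (15 of 19 called, median 2.17, camera adjusted p = 2.82e-16; 0.0656 with an estimated correlation) and fell in MEP (18 of 19 called, median -4.67, adjusted p = 5.28e-08; 0.153). Erythroid markers fell in GMP (13 of 20 called lower, 1 higher, median -3.24, adjusted p = 2.39e-07; 0.318) and rose in MEP (15 called, median 2.25, adjusted p = 1.11e-10; 0.153). Heme synthesis genes rose in MEP (13 of 16 called, median 1.49, adjusted p = 9.59e-09; 0.0686). Stem cell markers fell in GMP (median -1.68) and MEP (median -3.74), with adjusted p of 0.0107 and 0.0103 with an estimated correlation.

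In MEF, the same comparison of KO with WT called no gene by edgeR or limma-voom; 264 of 16506 genes had an unadjusted p under 0.05 and DESeq2 called 12. The targeted gene Zrsr2 was among the genes not called, at a log2 change of -6.54, so the lack of calls does not show a lack of effect. Sec14l1 had a log2 change of -0.30 and Spag1 of 0.91, each with an adjusted p of 1. Genes of fibroblasts and their matrix were higher as a list (15 of 18 higher, median 0.25, camera adjusted p = 9.37e-04), with periostin (Postn) at 0.48 and collagen gene Col1a1 at 0.31. Cholesterol synthesis genes (18 of 20 lower, median -0.18, adjusted p = 3.21e-03), glycolysis genes (17 of 19 lower, median -0.24, adjusted p = 1.74e-03, Gapdh at -0.33) and p53 targets (17 of 20 lower, median -0.16, adjusted p = 3.21e-03, Mdm2 at -0.39) fell. All 4 lists had an adjusted p of 0.854 with an estimated correlation. The 52 U12-type introns had a mean retention of 14.7 ± 1.29% in KO and 12.96 ± 1.085% in WT (SD, n = 3). Their median log2 ratio change lay 0.09 above that of other introns (29 of 52 higher, limma's camera p = 0.0198; p = 0.296 with an estimated correlation). That shift was 0.07905 to 0.2355 when 1 library was left out, and no longer passed without KO6 (0.08) or WT5 (0.14). No intron passed by edgeR, limma on the log2 ratio or the paired model, over all 32573 introns (573 at an unadjusted p under 0.05) or over the list alone. Pola2 intron 3 was at 14.8 ± 6.15% in KO and 6.94 ± 1.95% in WT. Without KO6 the gene count was 1.

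Lin-Kit+ cells with the control hairpin gave the KO effect in culture. No gene was called by edgeR or limma-voom, with 156 at an unadjusted p under 0.05 and 24 called by DESeq2; Spag1 had a log2 change of 1.58 and Sec14l1 of 0.06. With the experiment as a block 483 genes had an unadjusted p under 0.05 and 1 was called, the kidney gene Kap (adjusted p = 0.0425), which stood at 350.5 CPM in the WT control library of experiment 2. Markers of epithelial cells (6 of 7 lower, median -1.65, camera adjusted p = 5.72e-03; 0.447 with an estimated correlation) and neural cells (7 of 8 lower, median -0.64, adjusted p = 0.0122; 0.585) fell in KO. Proximal tubule genes summed to 713.4 CPM in that WT library and to 11.7 in the WT control of experiment 1. With the block, interferon-stimulated genes rose (30 of 30 higher, median 0.20, adjusted p = 4.21e-07, Bst2 at 0.41 and Irf7 at 0.34; 0.840 with an estimated correlation). U12-type introns were retained at 13.6 ± 1.74% in KO and 10.4 ± 0.802% in WT (SD, n = 2). Their shift over other introns was 0.20 (33 of 58 introns higher, limma's camera p = 0.0185; 0.401 with an estimated correlation). It was 0.44 in experiment 1 and -0.17 in experiment 2. Without the WT control of experiment 1 the shift was 0.04 and no longer passed the camera test, and 1 gene was called. Pola2 intron 3 rose by 4.05 with the block (SE 0.98, edgeR adjusted p = 9.61e-03), at 24.5 ± 21.3% in KO and 2.36 ± 2.72% in WT. Without the block no intron passed over all 46630 (435 at an unadjusted p under 0.05) or over the list, where Pola2 had 0.0589. The list count was 1 without the KO control of experiment 2 or the WT control of experiment 1.

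Hairpins against Zrsr1 in WT cells were compared with the control hairpin to ask what lower Zrsr1 does alone. Without a block no gene passed by edgeR or limma-voom, with 1312 at an unadjusted p under 0.05 and 386 called by DESeq2. With the experiment as a block 816 rose and 719 fell of 17592. With the block Alox15, an arachidonate lipoxygenase of macrophages and eosinophils, rose by 3.23 (SE 0.23, edgeR adjusted p = 3.61e-04), from 21.9 ± 16.1 to 203 ± 137 CPM (SD, n = 2 and 4, the 4 being sh1 and sh10 in 2 experiments). Apoc2, an apolipoprotein gene, rose by 2.69 (SE 0.25, 8.17e-04), from 20.5 ± 12.4 to 121 ± 66.5, and Itgax, the CD11c integrin chain, by 2.80 (SE 0.29, 1.18e-03). The stem and progenitor marker Cd34 fell by 1.62 (SE 0.13, 5.54e-04), from 198 ± 62.8 to 60.2 ± 18.6 CPM. Macrophage markers rose as a list (median 1.55, 12 of 16 called and 14 adjusted over the list alone, camera adjusted p = 6.08e-11), with the mannose receptor Mrc1 at 2.06, C1qb at 2.39 and Adgre1 at 1.03. Mitosis genes fell (median -0.62, 15 of 20 called, 20 over the list alone, adjusted p = 2.96e-15, Kif11 at -0.84 and Mki67 at -0.82). E2F targets fell too (9 of 20 called, 14 over the list alone, adjusted p = 9.67e-09, Mcm3 at -0.69). Neutrophil markers rose (5 of 15 called, 7 over the list alone, adjusted p = 2.48e-05, Ngp at 1.27). Interferon-stimulated genes rose (3 of 30 called, 9 over the list alone, adjusted p = 2.32e-05). With an estimated correlation the adjusted p was 0.342 for the macrophage, mitosis and E2F lists, 0.604 for neutrophils and 0.635 for interferon. Without the block the macrophage (adjusted p = 1.10e-05), mitosis (1.34e-05), neutrophil (1.27e-04) and E2F (5.33e-03) lists were called by camera too, each with 0.797 with an estimated correlation. Among the genes that fell most, Slc22a12 and Egf are kidney genes, at 35.3 and 54.0 CPM in the WT control of experiment 2 and 1.11 and 1.78 in that of experiment 1, while Plekhh1 and Celsr2 lay at 3.88 to 8.18 and 5.84 to 8.42 CPM in the controls. The blocked count was 164 without the WT control of experiment 2, and the unblocked count 7 without the WT control of experiment 1.

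The hairpins gave no called shift of U12-type introns in WT cells (median -0.10 against 0.07 for other introns, limma's camera p = 0.0680, and 0.510 with an estimated correlation). The shift passed the camera test without the WT sh10 library of experiment 2 (-0.13). Retention was 10.4 ± 0.802% with the control, 10.02 ± 2.98% with sh1 and 10.6 ± 0.925% with sh10 (SD, n = 2 each). The differences by experiment were 0.05 and -0.36 for sh1 and -0.21 and -0.42 for sh10. The values of experiment 2, -0.36 and -0.42, use the WT control library with kidney genes. No intron was called by edgeR or limma on the log2 ratio (418 at an unadjusted p under 0.05), and over the list alone 1 passed with the block. Intron 4 of the guanylate-binding protein gene Gbp6 (10 introns, chromosome 5, 105280272 to 105280454) fell by 3.17 (SE 0.65, list-adjusted p = 0.0460), at 0.823 ± 0.960% against 4.29 ± 2.29%.

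In KO cells the same hairpins again called no gene without a block by edgeR or limma-voom (1268 at an unadjusted p under 0.05, 382 by DESeq2) and 810 higher and 771 lower with it. With the block Alox15 rose by 3.32 (SE 0.23, edgeR adjusted p = 2.74e-04), from 23.5 ± 16.3 to 233 ± 162 CPM (SD, n = 2 and 4, the 4 being sh1 and sh10 in 2 experiments). The complement gene C1qa rose by 3.27 (SE 0.34, 1.23e-03) and Fcrls, a microglia and macrophage receptor-like gene, by 3.17 (SE 0.27, 6.59e-04). The endothelial growth factor gene Vegfc fell by 2.19 (SE 0.39, 9.41e-03) and the receptor gene Notch3 by 2.14 (SE 0.43, 0.0147). Macrophage markers rose (median 1.91, 12 of 16 called, 13 over the list alone, camera adjusted p = 5.13e-14, Mrc1 at 2.92). Mitosis genes (median -0.64, 16 of 20 called, 20 over the list alone, adjusted p = 1.79e-16, Ccna2 at -0.84 and Aurkb at -0.92) and E2F targets (10 of 20 called, adjusted p = 3.95e-11) fell. Core spliceosome genes fell (3 of 37 called, 11 over the list alone, adjusted p = 2.80e-06, Prpf31 at -0.44 and Sf3b3 at -0.38). Genes with a U12-type intron fell (median -0.25, 8 called lower and 2 higher of 63, adjusted p = 2.10e-03; 0.102 with an estimated correlation), with the small GTPase gene Arl2 at -0.83 and the chaperonin gene Tcp1 at -0.61. Their sums include the spliced reads of the U12-type intron, so this fall is not separate from its retention. With an estimated correlation the adjusted p was 0.168 for macrophages and 0.203 for the mitosis, E2F and spliceosome lists. Without the block camera called the macrophage (3.12e-07), mitosis (1.21e-06), E2F (3.25e-04) and spliceosome (1.60e-03) lists, each with 0.624 with an estimated correlation, and the genes with a U12-type intron (adjusted p = 0.0136; 0.347). Without the sh10 library of experiment 1 the unblocked count of genes was 3.

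**Figure D3:**
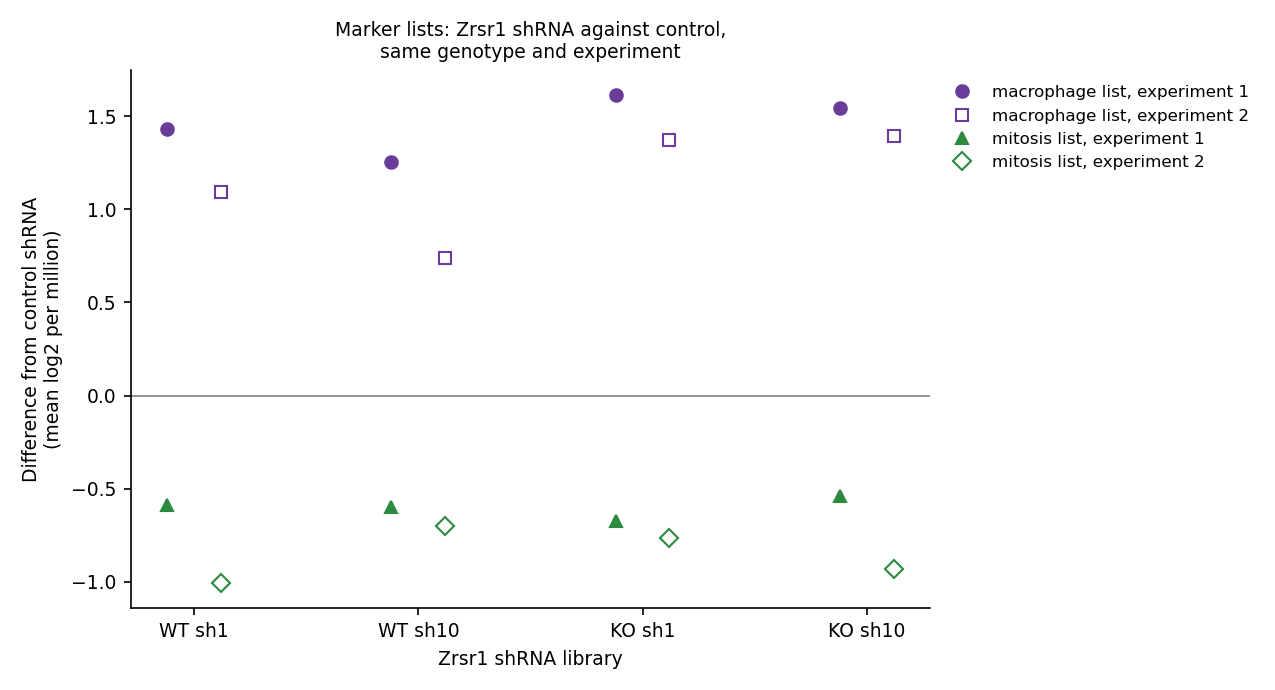
Mean log2 difference (CPM) of the macrophage and mitosis lists between each Zrsr1 hairpin library and the control library of the same genotype and experiment, 1 point per library; purple circles and squares are macrophage markers and green triangles and diamonds mitosis genes, filled for experiment 1 and open for experiment 2. The macrophage list lies above 0 and the mitosis list below 0 in all 8 libraries.

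U12-type introns in KO cells rose with the hairpins by a median log2 ratio of 0.71 against 0.02 for other introns (44 of 58 higher, camera p = 1.30e-04; 0.192 with an estimated correlation, and 0.0198 with that and the experiment as a block). Their mean retention was 13.6 ± 1.74% with the control, 17.6 ± 3.23% with sh1 and 19.5 ± 4.46% with sh10 (SD, n = 2 each). The shift over other introns was 0.36 and 0.42 for sh1 and 1.11 and 0.50 for sh10 in experiments 1 and 2. No single intron passed by edgeR or limma on the log2 ratio, over all introns (873 at an unadjusted p under 0.05) or over the list alone, with or without the block. The hairpin effect on the class was higher in KO than in WT by 0.77 (42 of 58 introns, camera p = 2.65e-05; 0.158 with an estimated correlation, and 0.0132 with that and the block). By hairpin and experiment that difference was 0.32 and 0.79 for sh1 and 1.32 and 0.92 for sh10. The values of experiment 2, 0.79 and 0.92, use the WT control library with kidney genes. Between genotypes the hairpin effect differed for no gene (edgeR and limma-voom 0, DESeq2 12, 228 at an unadjusted p under 0.05, and 0 with the block). It differed for 1 gene without the WT control or the KO sh10 library of experiment 1. Erythroid progenitor markers (16 of 20 higher, median 0.32, camera adjusted p = 0.0119; 0.806 with an estimated correlation) and epithelial markers (median 1.60, adjusted p = 7.01e-03; 0.410) rose in that difference, which includes the WT control library with kidney genes. Genes with a U12-type intron fell (41 of 63 lower, median -0.11, adjusted p = 0.0135; 0.378), again with that intron in their sums. With the block the number of called lists was 6 in place of 2, with interferon-stimulated genes lower (30 of 30, median -0.25, adjusted p = 1.43e-06) and mast cell markers higher (17 of 17, adjusted p = 9.88e-04). Their adjusted p was 0.747 and 0.659 with an estimated correlation.

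KO and WT cells that both carried a Zrsr1 hairpin differed in U12-type introns. This comparison was added after the data were seen. The median log2 ratio change of the 58 U12-type introns was 1.21 against -0.07 for other introns, a shift of 1.27 (48 of 58 higher, camera p = 3.26e-19; p = 0.0136 with an estimated correlation). Within experiments 1 and 2 it was 0.76 and 0.90 for sh1 and 1.56 and 0.76 for sh10. Pola2 intron 3 was retained at 50.9 ± 17.3% in KO and 4.13 ± 1.55% in WT (SD, n = 4 libraries, sh1 and sh10 in 2 experiments), a rise of 4.62 (SE 0.92, edgeR p adjusted over the list alone = 1.05e-03). Over all introns 0 passed without the block by edgeR, limma or the paired model (1023 at an unadjusted p under 0.05) and 14 with it. Those were led by Pola2 (adjusted p = 2.30e-07), intron 21 of Inpp5b (23 introns, chromosome 4, 124797910 to 124798251; 27.2 ± 14.3% against 6.13 ± 4.52%, 1.58e-05) and intron 4 of Mcts1 (48.9 ± 4.26% against 12.1 ± 5.90%, 5.55e-05). Introns of the RNA-binding protein gene Hnrnpm, the tetraspanin gene Tspan31, the splicing factor gene Ik and the sorcin gene Sri rose too, by 2.49, 2.25, 2.34 and 1.91. Of these 14 introns, 1 was U12-type by the main rule (Pola2) and 3 by the exact 5′ site only. The rest were classed as other or could not be classed. Over the list alone 11 passed with the block, among them intron 13 of Vps16 (38.4 ± 9.09% against 13.4 ± 3.73%) and intron 13 of the membrane receptor gene Lmbr1l (47.45 ± 8.01% against 13.8 ± 9.01%). The others included intron 4 of the cell cycle repressor gene E2f6 (29.1 ± 3.48% against 6.34 ± 4.70%) and intron 5 of Tcp1 (8.71 ± 3.46% against 3.08 ± 0.948%). Without the block that count was 1, or 4 without the WT sh10 library and 2 without the WT sh1 library of experiment 1, and 0 with sh1 alone.

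At the level of genes, few calls were made in the same comparison. Without the block edgeR and limma-voom called 0 genes (343 at an unadjusted p under 0.05; DESeq2 25). With it edgeR called 5, named after their values were seen apart from Zrsr2 (log2 -6.18, SE 0.75, adjusted p = 0.0390). The interferon-inducible gene Ifi202b rose by 2.75 (adjusted p = 8.94e-03), Gm18445 by 2.74 (8.94e-03), Gm42047 by 1.06 (0.0390) and Taf2, a subunit of the general transcription factor TFIID, by 0.93 (0.0390). Ifi202b ranged from 1.05 to 69.7 CPM among the WT CMP libraries, so it varies between mice of 1 genotype. Whether its rise here follows the KO or the mice was not tested. Mast cell and basophil markers rose (17 of 17 higher, median 0.65, camera adjusted p = 3.40e-07), with Epx at 0.67 and Mcpt8 at 0.76. Markers of macrophages (14 of 16 higher, median 0.41, adjusted p = 8.42e-04) and megakaryocytes (13 of 15 higher, median 0.37, adjusted p = 4.43e-03, Pf4 at 0.93) rose as well. All 3 had an adjusted p of 0.709 with an estimated correlation. Erythroid markers rose (18 of 20 higher, median 0.46, adjusted p = 2.36e-05; 0.526). Genes with a U12-type intron fell (42 of 63 lower, median -0.10, adjusted p = 0.0150; 0.359), and with the block both tests called them (adjusted p = 1.04e-03, and 0.0402 with an estimated correlation). Their sums include the spliced reads of the U12-type introns, which changed by a median log2 of -0.271 here (7 of 58 higher). The fall of these genes is therefore not separate from retention. The block moved the number of called lists to 9, adding lower E2F targets (median -0.16, adjusted p = 9.80e-05; 0.448 with an estimated correlation). Without the KO sh10 library of experiment 1 edgeR called 6 genes without a block.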

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

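Of the tests in this part, the added comparison of KO with WT under Zrsr1 hairpins, the camera test of the U12-type class, the lists of kidney and other organ genes, both tests of the kidney signal, and the tests of kidney RNA and of intron retention as a source of the hairpin genes were chosen after the result was seen.

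Several results stood out because the effect differed between groups in a test of the difference. The KO effect on Syne2, a nuclear envelope gene, was higher in MEP than in CMP by 3.892 and than in GMP by 3.901 on the log2 scale, and that on Rdh12, a retinol dehydrogenase gene, by 2.832 and 2.883. Both genes were near the floor of detection in WT MEP. With the mouse as a random effect or with limma-voom neither passed in either comparison. The log2 ratio of Washc5 intron 14 differed between MEP and CMP by -8.203, a value that depends on the pseudocount because retention was 0% in 6 of the 12 libraries. Its call was lost with the mouse number as a block. Between GMP and CMP the KO effect differed by a median of -0.2563 for markers of granulocyte-monocyte progenitors and by -1.465 for mature neutrophil markers, both with an adjusted p of 0.991 with an estimated correlation. The hairpin effect in KO minus that in WT Lin-Kit+ cells was 1.598 for epithelial markers, 0.3193 for erythroid progenitor markers, -0.1107 for genes with a U12-type intron and 0.766 for the U12-type shift. With an estimated correlation the adjusted p of the 3 lists was 0.410, 0.806 and 0.378, and the p of the shift 0.158, or 0.0132 with the block as well. The epithelial value includes the WT control library with kidney genes.

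The covered fraction of introns, a column that the comparisons above did not use, also differed between U12-type and other introns in part of the comparisons. The change in KO minus WT CMP was higher by 0.05671 for U12-type introns (camera p = 5.75e-05, and 0.0361 with an estimated correlation). In Lin-Kit+ cells it was -0.03505 for hairpins in WT (camera p = 8.77e-03, and 0.553 with an estimated correlation), 0.04394 for hairpins in KO (0.0200, and 0.597) and 0.1158 for KO against WT with hairpins (1.37e-09, and 0.196). The KO effect did not pass the camera test in GMP (0.0152), MEP (0.0327), MEF (0.00506) or Lin-Kit+ cells with the control hairpin (0.0368). The change in GMP minus that in CMP was -0.0415 (0.0108, and 0.161 with an estimated correlation), while that in MEP minus CMP (-0.0240) and in MEP minus GMP (0.0174) did not pass. The hairpin effect in KO minus that in WT was 0.0790 (camera p = 3.40e-04, and 0.423 with an estimated correlation).

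The first pattern weighed is the higher retention of U12-type introns in KO than in WT cells that both carried a Zrsr1 hairpin. More unspliced RNA or genomic DNA would raise other introns of the same genes as much, but U12-type introns exceeded them by a median of 0.975 (57 introns, 95% bootstrap interval over introns, not libraries, 0.497 to 1.42, 44 above 0), and the shift over other introns was 0.76 to 1.56 in each hairpin and experiment. Low complexity of the libraries of experiment 2 is argued against by experiment 1 alone, where the lower of the hairpins' shifts was 0.7609. A loss of spliced reads only is argued against by CPM values of exon-intron reads, which changed by a median of 0.7695 (interval over introns 0.629 to 1.13, 46 of 58 introns higher), while spliced reads changed by -0.271 (interval -0.407 to -0.167). Loss of both genes stays open, as do off-target effects shared by both hairpins: the hairpin effect was higher in KO than in WT for both hairpins in both experiments, with 0.3194 as the lowest of the 4 differences, but these are parts of the 0.766 given above, sh1 and sh10 share their control libraries, and the knockdown was not measurable. The differences of experiment 2 also use the WT control library with kidney genes.

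The second pattern weighed is the set of genes called between Zrsr1 hairpin and control libraries once the experiment is a block. Kidney RNA in the WT control of experiment 2 is argued against as the whole source by the KO comparison, which does not use that library and called 1581 genes. That does not show how many of the WT calls depend on the library. Retention of U12-type introns is argued against for the genes called in WT by a U12-type shift of -0.17 within WT. That shift also argues against retention for the 575 higher and 444 lower genes called in both WT and KO. For the other genes called in KO retention stays open, as the shift in KO was 0.69. Of those 1581 genes, 97.6% changed the same way in WT with sh1 and 95.32% with sh10, which argues against a single hairpin. In 8 of 8 hairpin libraries the macrophage list lay above and the mitosis list below the control library, but sh1 and sh10 share each control and both lists were called in these same libraries, so this is no separate test of more mature and less proliferating cells, which stay open. An origin in lower Zrsr1, in the hairpins themselves or in the cultures was not tested.

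The third pattern weighed is kidney transcripts in the WT control library of experiment 2, with Kap at 350.5, Slc34a1 at 102.0 and Umod at 98.6 CPM. All 18 of 18 measured tubule genes were highest of the 36 libraries in this one, against 3 of 29 genes (10.3%) of liver, intestine, pancreas and lung, and 0 of 2 podocyte genes, of which Nphs1 cannot be read, since introns of Kirrel2 hold nearly the same counts in experiment 1. An effect of the WT control condition is argued against by the WT control of experiment 1, where proximal tubule genes summed to 11.74 CPM, within the 3.22 to 12.9 of the other 10 Lin-Kit+ libraries, against 713.4 here. RNA or reads from kidney may be the source, which a sort for Kit and against lineage markers before culture should have removed; whether they entered with the cells or as another library was not tested.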

How the results depend on the processing

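The rule with the exact 5′ site only, the camera shift of U12-type introns and its estimated correlation, the paired quasi-likelihood model, the median intron count per gene, single hairpins in intron tests, the comparison of KO with WT under Zrsr1 hairpins and blocked fits with DESeq2, limma-voom, the median intron count or 1 library fewer were chosen after the data were seen. Over all alternatives, values that answer a comparison stayed as reported under 627 settings, moved under 172, lost a call under 17, gained 1 under 9 and reversed under 13. Named genes and introns kept their call under 328 settings, lost it under 184 and reversed under 0. The cause was not tested for any change below, except that leaving out a library or fitting 2 groups leaves fewer samples. Average transcript length offsets and the summing of transcripts were not run, since the tables are not per transcript.

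Counts of called genes under DESeq2 were 48 in CMP, 20 in GMP, 80 in MEP, 10 for GMP against CMP, 46 for MEP against CMP, 39 for MEP against GMP, 12 in MEF, 24 for KO in Lin-Kit+ cells with the control, 386 for hairpins in WT, 382 for hairpins in KO, 12 for the difference between genotypes and 25 for KO against WT with hairpins. The median intron count per gene gave 1 in CMP, 1 in GMP, 2 in MEP, 1 for MEP against CMP, 0 for MEP against GMP and 1 in MEF. A fit on the 2 groups alone gave 1 in each progenitor type. With the mouse as a random effect or with limma-voom the count was 2 in MEP and 0 for MEP against CMP or GMP. With no filter on low counts it was 13 in MEP, 1 for MEP against CMP, 11 for KO with the control hairpin, 121 and 47 for hairpins in WT and KO, and 13 for KO against WT with hairpins. With sh10 alone it was 4 for hairpins in WT.

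The replicate block in Lin-Kit+ cells is the experiment. It moved the gene counts to 1 for KO with the control hairpin, 1535 and 1581 for hairpins in WT and KO, and 5 for KO against WT with hairpins. The block with DESeq2 gave 32, 2585, 2577 and 103, and 28 for the difference between genotypes; with limma-voom 1910 and 1586 for the hairpins and 2 for KO against WT; with the median intron count 1110, 1125 and 5; and without the WT control of experiment 2, 164 for hairpins in WT. Introns called with the block were 1 for KO with the control hairpin and 14 for KO against WT with hairpins, and over the list alone 1, 11 and, for hairpins in WT, 1. Called lists were 6 for the difference between genotypes and 9 for KO against WT with hairpins. KO and WT mice share a number, which was not treated as a pair in the main fits. Correlations of same-numbered libraries were 0.0259 to 0.0436 in CMP, -0.0036 to 0.0862 in GMP, 0.0677 to 0.1586 in MEP and -0.0983 to 0.4378 in MEF (3 pairs each). Every library correlated best with its own number in CMP and MEP but not in GMP or MEF. Whether a shared number marks a pair was not tested. A block on that number gave 4 introns in CMP, 2 in GMP and 0 for MEP against CMP, 1 gene for MEP against CMP, and 5, 1 and 3 called lists in CMP, MEP against CMP and MEP against GMP. It changed no other count of calls by over 1.5 times.

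Introns called over all tested were 5 in CMP with at least 50 counts, 7 in CMP, 11 in MEP and 0 for MEP against CMP with limma on the log2 ratio, and 0 in CMP, GMP, MEP and MEP against CMP with the paired model. Over the list alone, the exact 5′ site gave 8 in CMP, 7 in GMP, 7 in MEP, 1 in MEF and 4 for KO against WT with hairpins; limma gave 4 in CMP, 6 in GMP and 2 for KO against WT with hairpins; the paired model 4 in CMP and 2 for that comparison. At least 50 counts gave 2 in MEP, 1 for KO with the control hairpin and 6 for KO against WT with hairpins, the strict rule 1 for KO with the control hairpin, and sh1 alone 0 for KO against WT with hairpins.

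The U12-type shift of MEP against CMP reversed to -0.129 with the exact 5′ site only. Its call was lost in MEF at 0.0311 with that rule and at 0.09197 with an estimated correlation. In Lin-Kit+ cells with the control hairpin it was lost at 0.02881 under the strict rule, 0.1881 with at least 50 counts and 0.1969 with an estimated correlation. The estimated correlation also ended the calls of 0.6933 for hairpins in KO and 0.766 for the difference between genotypes. With at least 50 counts the shift for hairpins in WT, -0.1924, was called. With an estimated correlation and without a block 0 fixed lists were called in CMP, GMP, MEP, GMP against CMP, MEF and all 5 Lin-Kit+ comparisons.

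The median change of genes with a U12-type intron was close to 0 in most comparisons and reversed to 0.002721 in CMP with the replicate block. With the exact 5′ site only it reversed to 0.003463 in GMP, 0.03284 for GMP against CMP and -0.01125 for KO with the control hairpin. A list written by hand reversed it to -0.0007969 in MEP, 0.02208 for GMP against CMP, -0.0039 for MEP against GMP, -0.01723 for KO with the control hairpin and 0.0006967 for the difference between genotypes, and the strict rule to 0.01252 for GMP against CMP. Calls were lost for hairpins in KO (-0.1042 with the exact 5′ site, -0.1326 with the hand list, -0.2297 with an estimated correlation), the difference between genotypes (-0.09343 and, with an estimated correlation, -0.1107) and KO against WT with hairpins (-0.06833 and -0.09684).

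Leaving out 1 library at a time gave 1 to 2 genes in CMP, 1 to 5 in GMP, 7 to 15 in MEP, 0 to 1 for GMP against CMP, 1 to 4 for MEP against CMP, 1 to 6 for MEP against GMP, 0 to 1 in MEF, 0 to 1 for KO with the control hairpin, 0 to 7 and 0 to 3 for hairpins in WT and KO, 0 to 1 for the difference between genotypes and 0 to 6 for KO against WT with hairpins. Between WT cell types it gave 3252 to 3962 genes for GMP and 7217 to 7777 for MEP. Introns over all tested were 0 to 2 in CMP, 1 to 2 in GMP, 1 to 3 in MEP, 0 to 1 for MEP against CMP and 0 elsewhere. Over the list they were 2 to 5 in CMP, 1 to 7 in GMP, 2 to 4 in MEP, 0 to 1 for MEP against CMP and for KO with the control hairpin, 1 to 4 for KO against WT with hairpins and 0 elsewhere. The U12-type shift was 0.292 to 0.4622 in CMP, 0.4667 to 0.5656 in GMP, 0.2554 to 0.4476 in MEP, 0.1801 to 0.3373 for GMP against CMP, -0.007656 to 0.1063 for MEP against CMP, -0.2806 to -0.0706 for MEP against GMP, 0.07905 to 0.2355 in MEF, 0.03794 to 0.5005 for KO with the control hairpin, -0.401 to -0.01229 and 0.4868 to 0.7412 for hairpins in WT and KO, 0.5835 to 1.023 for the difference between genotypes and 1.138 to 1.353 for KO against WT with hairpins. Where this left 1 library in a group, that library was assumed to vary like the others of the fit.

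Simulated log2 changes of 1 and 2 were recovered for 5 and 50 of 100 introns in CMP, 8 and 74 in MEF and 0 and 0 in Lin-Kit+ cells with the control hairpin, against 60 and 86, 33 and 79, and 0 and 13 of 100 genes. Changes of single introns of that size were therefore not detectable between KO and WT Lin-Kit+ cells with the control hairpin, without a block and with 2 libraries per group. The other Lin-Kit+ comparisons were not simulated. The simulated shares for MEF may be too high, as edgeR did not call Zrsr2 there at a log2 change of -6.54. In experiment 2, 30.6 to 37.0% of introns with at least 20 exon-intron reads had none at 1 of the 2 ends.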

Other observations

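The tests of overlap between genotypes and of sh1 against sh10 in this part were chosen after the result was seen; the splits of the samples were planned.

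Hairpin effects in WT and KO Lin-Kit+ cells fell on many of the same genes with the experiment as a block, in comparisons that use separate control libraries. Of 816 genes higher in WT and 810 in KO, 575 were shared, where independent lists would share 37.6, and of 719 and 771 lower genes 444 were shared, where independent lists would share 31.5. In opposite directions 0 genes were called. The numbers for independent lists assume that every gene is equally easy to call. Both comparisons come from 1 fit, where genes with low spread are easier to call in both, so these numbers are too low a base. Alox15, Dnah2 and Grm6 were among the shared higher genes, with Grm6, a glutamate receptor gene, at 2.97 in WT (SE 0.23, edgeR adjusted p = 5.54e-04) and 3.20 in KO (SE 0.24, adjusted p = 2.74e-04). Cdh1, the E-cadherin gene, rose by 0.91 in WT and by 1.80 in KO (SE 0.14 in KO, adjusted p = 4.60e-04). The hairpins also differed from each other: sh1 against sh10 called 1070 genes in WT and 328 in KO.

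Reads that span many introns show in Nphs1, a podocyte gene, where 24 of 26 introns hold exactly 329 spliced reads in the WT control library of experiment 1. Introns of Kirrel2 hold 329 reads in that library too, so these counts cannot be assigned to Nphs1. The median count per Nphs1 intron was 192 to 585 in the libraries of experiment 1 and 0 to 5 in those of experiment 2. Genes with at least 5 introns were screened for even counts, within 10% over all their listed introns and with a median of at least 20 reads. Of 14054 such genes, 432 were found in progenitors, 142 in MEF and 306 in Lin-Kit+ cells. Genes with fewer reads, or with any intron that departs from the rest, cannot be found this way. Nphs1 is missed too, as its lowest intron holds 1 read in that WT control library, so these numbers are lower limits. Of the 2099 genes called in Lin-Kit+ cells with the block, 11 were among them.

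In MEP, summed spliced counts of Syne2 over 114 introns were 216, 156 and 131 in KO and 11, 12 and 10 in WT, of Rdh12 over 6 introns 26, 36 and 47 against 5, 8 and 3, of F10 over 8 introns 53, 65 and 28 against 11, 3 and 4, of Tlr7 over 5 introns 27, 20 and 10 against 0 in each, and of Irf5 over 9 introns 43, 111 and 56 against 23, 7 and 19. A read is counted at each intron it crosses: in KO2, Rdh12 had 6 reads at every intron, F10 8 to 9 and Tlr7 4, and in KO3 Tlr7 had 2 at every intron.

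Splits of 6 mice into groups of 3 number 10, the real one included, too few for a share under 0.05, so the real value and the highest other are given, in part with the number of splits that reach the real value. For called genes these were 3 and 2 in CMP (the real count was reached by 1 split, itself included), 3 and 3 in GMP (2 splits), 8 and 66 in MEP (6 splits), 0 and 0 for GMP against CMP (10 splits), 2 and 2 for MEP against CMP (2 splits), 2 and 8 for MEP against GMP (3 splits) and 0 and 488 in MEF (10 splits). The real counts in CMP, GMP and MEP include Zrsr2, whose fall the knockout fixed in advance. Without Zrsr2 the CMP count does not exceed the highest other split. The splits that called 66 genes in MEP and 488 in MEF, the latter 1 split whose next highest called 2, point to some structure of the samples that was not tested further. For introns over all tested the values were 2 and 1 in CMP, 4 and 1 in GMP, 3 and 1 in MEP, 0 and 1 for GMP against CMP, 1 and 0 for MEP against CMP, 0 and 3 for MEP against GMP and 0 and 1 in MEF. For U12-type introns over the list alone they were 2 and 1 in CMP, 3 and 1 in GMP, 4 and 0 in MEP, 0 and 1 for GMP against CMP, and 0 and 0 for the other 3 comparisons. For the U12-type shift they were 0.35 and 0.25 in CMP, 0.50 and 0.28 in GMP, 0.29 and 0.21 in MEP, 0.26 and 0.29 for GMP against CMP (2 splits), 0.04 and 0.13 for MEP against CMP (7 splits), -0.11 and 0.22 for MEP against GMP (6 splits) and 0.09 and 0.17 in MEF (3 splits). For lists called by camera they were 3 and 8 in CMP (10 splits), 3 and 7 in GMP (7 splits), 4 and 10 in MEP (6 splits), 2 and 5 for GMP against CMP (4 splits), 0 and 7 for both comparisons with MEP (10 splits) and 4 and 12 in MEF (10 splits). For differences between WT cell types, the 6 libraries of 3 WT mice were split without regard to the mouse. The real split gave 4290 genes against at most 0 in another split for GMP and 8066 against at most 1 for MEP. Every other split mixes 2 unlike cell types, so a low count was likely in advance and these values do not test chance.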
